A study of Mus musculus with 13 samples.

How the data were processed

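The data were TAB-seq measurements of 5hmC in 13 PyMT-induced breast tumours, 1 per mouse as the labels describe them. Per the labels' protocols, tumours were snap-frozen, DNA was extracted in buffers with 200 µM of the iron chelator DFO, libraries were TAB-converted and bisulfite-treated with a commercial kit, and they were amplified with a uracil-tolerant polymerase. The authors deposited 1 table, in percent: the 5hmC percentage in each of 9097 bins of 300 kb, with 1 column per tumour. Bismark 0.13.1 and mm9 are named in the submitters' processing notes, with no role given. How calls were pooled within a bin, any coverage minimum, and conversion or protection rates of spike-in controls are not given in the sources used here. Without read counts, depth is unknown, and the test of methylated against unmethylated counts was not possible. A bin with few reads weighs as much as any other, and a 0 can stand for no 5hmC or for no data: the first 3 Mb of the autosomes and X, 200 bins, were 0 in all tumours.

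The last bin of each chromosome ended at the length of GRCm38 and not of mm9 (chromosome 1 at 195471971), so coordinates are given as GRCm38. The design fixed before the data were examined named genes only with mm9 annotation and by transcription start. As the bins were GRCm38 and the gene table given (GRCm38.p6, RefSeq) has no strand, each gene was instead assigned to the bin holding most of its body, a departure from that design made after the build was seen. As a check, the correlation of gene density with 5hmC was computed with genes shifted by up to 30 bins; it was highest with no shift on 19 of 20 chromosomes. All 116 genes of the 10 lists (hypoxia-inducible, endothelial, luminal, basal, fibroblast, immune, tumour suppressor, cytosine modification, Polycomb target and housekeeping genes) matched.

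Groups were taken from the sample titles and columns matched by the labels' descriptions. Bins of chromosome Y and the mitochondrial genome, and those at 0 in all 13 tumours, were left out, which kept 8576 bins. The design had asked for bins measured in all tumours; keeping 0 as a value was decided after the zeros were seen, and the 7338 bins above 0 in all tumours were run as an alternative. The genome-wide value of a tumour is the unweighted mean over bins. Groups were compared by exact two-sided permutation of the difference of means, with labels permuted within each model for tests over both. For a difference between models, the null of that permutation is no effect in either model, not equal effects. The SE of a difference came from the group SDs. Bins, and the mean percentages of 20 chromosomes, were tested with limma 3.58.1 in R 4.3.3 on percentages, all 13 tumours in 1 fit with 4 group means, with a trend for bins and without one for chromosomes, and Benjamini-Hochberg adjustment at 0.05. The SE of a bin or chromosome is limma's, and within a comparison it was the same for all 20 chromosomes. limma assumes a shared spread and approximately normal values, which bins with many zeros do not meet. Level classes were 5 equal groups of bins by their mean over all 13 tumours. Chromosome ends were the last 3 Mb. Gene lists were tested by exact permutation relative to the genome-wide mean, as a difference or, where stated, as a ratio, and by limma's camera and fry.

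The genes and bins named were chosen by a rule fixed before the data were examined: in each main comparison up to 10 bins in each direction past the threshold or, where fewer passed, the 5 with the smallest p in each direction, the chromosomes with the largest and smallest difference, and from each list the 2 genes with the smallest p. Values of some genes this rule takes are not reported here. Egln1 and the highest bins in the closing section were named after their values were seen. Listed genes share bins in places, as Krt8 and Krt18 do.

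The limma step was tested on simulated data with the means and spread of these tumours, with 200 of 8576 bins changed. With 2 percentage points added, 1 of 6 calls was false in the sFlk1 design and 7 of 52 in the Phd2 design. With 4 added, 9 of 170 and 15 of 182 were false, and with 6 added, 5 of 178 and 12 of 198. The share of false calls was thus above the 5% aimed at in all but 1 of these, and a simulation without change gave 0 calls. Alternatives fixed before the data were examined were medians over bins, autosomes alone, removal of bins over 5 median absolute deviations from the median bin, log2 and arcsine scales, scaling to the sample median, removal of the lowest 10% of bins, only the 2 groups of a contrast in the fit, no trend, sample weights, 3 Mb windows, the replicate number as a block for genome-wide values and bins, and each tumour left out for genome-wide values, bins, chromosomes and level classes. Those added later were bins above 0 in all tumours, chromosomes relative to the tumour's mean or with the replicate number as a block, and the alternatives to the 3 Mb windows. Added later too were each tumour left out for the X ratio, chromosome ends, the gap between highest and lowest class, the share of bins, the lists and the control groups, and the trends and autosomes alone for shared regional effects. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.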

Results

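5-hydroxymethylcytosine (5hmC), the base that TET enzymes make from 5-methylcytosine using oxygen, was measured at shallow depth by tet-assisted bisulfite sequencing (TAB-seq) in 13 breast tumours of FVB mice, induced by the polyoma middle T oncogene (PyMT). In TAB-seq, 5hmC is protected before oxidation and conversion, so that a cytosine that still reads as cytosine stands for 5hmC. Tumours came from 2 mouse models in which the blood supply differed. In one, 16-week-old mice were Phd2 wild type (n = 3) or Phd2 heterozygous (n = 4), and the labels describe the heterozygous tumours as better perfused and oxygenated. In the other, 12-week-old mice had been injected with an empty plasmid (n = 3) or with a plasmid for sFlk1 (n = 3), a soluble VEGF receptor, which the labels describe as making tumours more hypoxic. The values were 5hmC percentages in 300 kb bins. Read counts were not part of the table, so the depth of each sample is unknown and no interval from counting can be given. Profiles of tumours of the same group correlated across bins with Pearson r of 0.716 to 0.873 over 15 pairs, and those of different groups with r of 0.738 to 0.885 over 63 pairs. Bins are not independent replicates. The sFlk1 profiles correlated least within their group, with a median r of 0.741, against 0.855 among Phd2 heterozygous tumours. Yet sFlk1 tumour 1 had r of 0.827 with Phd2 wild-type tumour 3, above its 0.747 and 0.741 with sFlk1 tumours 2 and 3. Neighbouring bins correlated at 0.461 to 0.494 in sFlk1 tumours and at 0.494 to 0.559 in the others. Noisier profiles and real differences between sFlk1 tumours cannot be told apart.

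**Figure D1:**
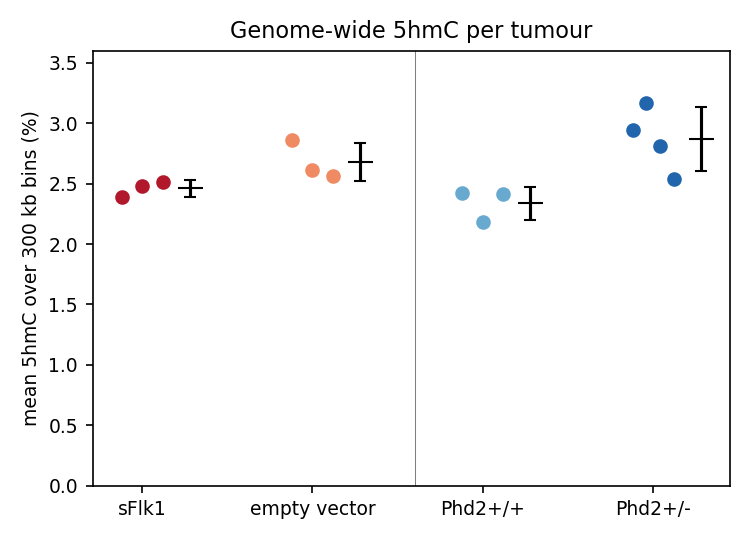
Mean 5hmC percentage over 8576 bins of 300 kb (vertical axis) for each of the 13 tumours (points) in the 4 groups, with the group mean and SD beside them (black). Within each model the tumours of the 2 groups do not overlap: sFlk1 tumours lie between 2.39% and 2.52%, empty vector tumours between 2.57% and 2.86%, Phd2 wild-type tumours between 2.18% and 2.42% and Phd2 heterozygous tumours between 2.54% and 3.17%.

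The comparison of Phd2 heterozygous with wild-type tumours asks whether 5hmC differs genome-wide when tumour oxygenation is restored. Mean 5hmC was 2.87% ± 0.265 (SD, n = 4) in Phd2 heterozygous tumours and 2.34% ± 0.137 (SD, n = 3) in wild-type tumours, a difference of 0.527 percentage points (SE 0.154) or 22.5%. The difference was widest where 5hmC was high. Bins were put into 5 equal classes by level. In the highest class the means were 5.95% ± 0.581 (SD, n = 4) and 4.67% ± 0.366 (SD, n = 3). In the lowest class they were 0.577% ± 0.0808 and 0.575% ± 0.0202. All 4 heterozygous tumours lay above all 3 wild-type tumours in the genome-wide mean. The exact two-sided permutation test gave p = 0.0571, where the smallest value that 35 arrangements allow is 0.0286. So the genome-wide difference did not pass 0.05 within this model alone. With medians over bins the groups overlapped: heterozygous tumour 4 (2.07%) lay below wild-type tumours 1 and 3 (2.13% each). The difference of medians was 0.412 percentage points (exact permutation p = 0.114). The highest class gave an exact p of 0.0286, which was 0.143 after adjustment over the 5 classes. The difference between the highest and the lowest class was 1.28 percentage points larger in heterozygous tumours (SE 0.372, exact permutation p = 0.0286). That last p is the smallest the design allows, and it was lost whenever 1 tumour was left out, since fewer arrangements then remain. Of all bins, 75.2% had a higher mean in heterozygous tumours (exact permutation p = 0.114).

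**Figure D2:**
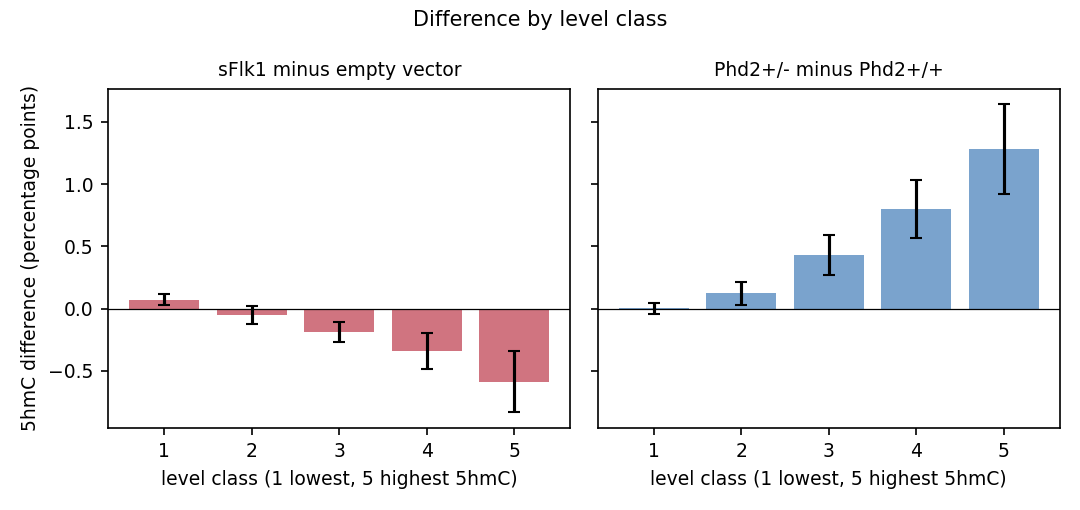
Difference in mean 5hmC in percentage points (vertical axis, bars) for bins in 5 classes by their mean over all 13 tumours (horizontal axis), with SE as error bars, for sFlk1 minus empty vector (left, n = 3 and 3) and Phd2 heterozygous minus wild type (right, n = 4 and 3). The bars run from 0.0703 to -0.589 on the left and from 0.00186 to 1.28 on the right.

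By chromosome, 5hmC was higher in Phd2 heterozygous tumours on all 20 chromosomes, by 15.6% on X to 26.6% on chromosome 14. The largest difference in percentage points was on chromosome 11 (3.49% ± 0.331 against 2.82% ± 0.271, SD, n = 4 and 3; difference 0.668, SE 0.150, limma adjusted p = 1.63e-04) and the smallest on X (1.34% ± 0.0977 against 1.16% ± 0.0404; difference 0.180, SE 0.150, limma adjusted p = 0.229). With limma, 19 chromosomes passed, all but X. The fit shared the spread between groups and also across chromosomes, so each chromosome had the same SE of 0.150. As the chromosomes of a tumour move together, these limma p-values overstate the evidence. X, whose SDs were lower than those of any autosome in both groups, was judged by that shared SE. The chromosomes are 20 readings of 1 genome-wide shift in the same tumours and not 20 separate results. The exact permutation p was 0.0571 on 18 autosomes and 0.0286 on chromosome 19, and relative to each tumour's own mean 0 chromosomes passed.

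**Figure D3:**
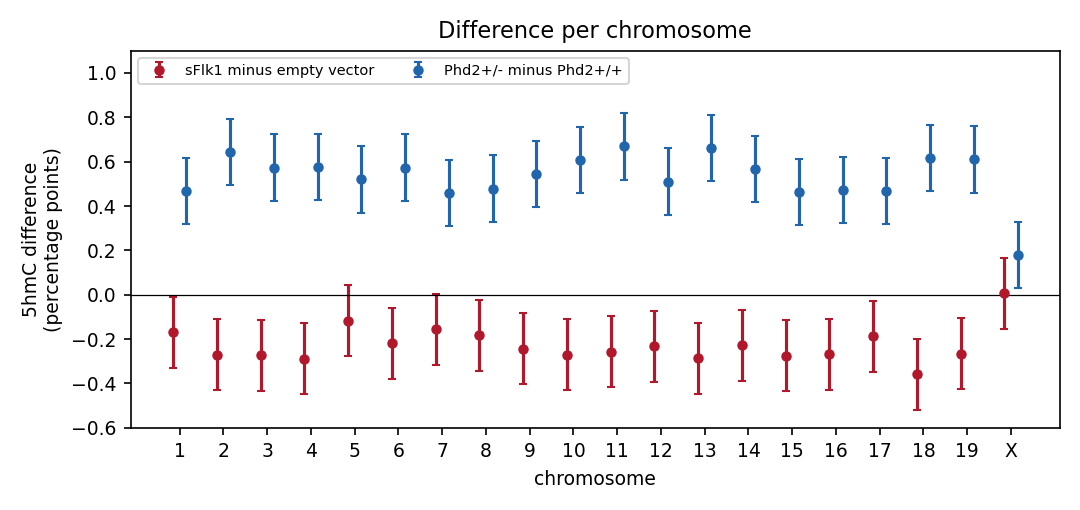
Difference in mean 5hmC in percentage points (vertical axis) on each of 20 chromosomes (horizontal axis), with SE from limma as error bars, for sFlk1 minus empty vector (red) and Phd2 heterozygous minus wild type (blue). Blue points lie above 0 throughout, and red points lie below 0 on 19 chromosomes, with X at 0.00641.

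At the level of gene groups, 5hmC in the bins of luminal epithelial genes was 4.77% ± 0.224 (SD, n = 4) in Phd2 heterozygous and 3.77% ± 0.504 (SD, n = 3) in wild-type tumours, and in the bins of tumour suppressor genes 5.26% ± 0.599 and 4.04% ± 0.379. Each value belongs to a 300 kb bin and its other genes too. The bin of Gata3, a luminal transcription factor, held 7.16% ± 1.47 against 4.27% ± 0.90, and that of Cdh1, which encodes E-cadherin, 5.95% ± 0.901 against 4.06% ± 1.22. The bin of Nf1, a Ras regulator, held 9.35% ± 2.21 against 6.24% ± 1.88, and that of Vhl, part of the ligase that degrades HIF, 5.94% ± 1.66 against 4.14% ± 0.981. Relative to the genome-wide mean, 0 of the 10 lists passed the exact permutation test after adjustment. The lowest adjusted p was 0.286. The luminal list had an unadjusted exact p of 0.0286, the smallest that 35 arrangements allow. After adjustment over 10 lists, a single list could therefore not pass on its own. Taken as a ratio to the genome-wide mean, the luminal list had an unadjusted exact permutation p of 0.543. As a difference over every bin that its gene bodies overlap, the exact permutation p was 0.257. The luminal bins held 1.62 times the genome-wide mean, and differences were wider where 5hmC was high. The set test fry, which asks only whether the bins of a list move one way on balance, called housekeeping (adjusted p = 0.0346), luminal epithelial (0.0390), tumour suppressor (0.0390) and cytosine modification genes (0.0498) higher. Camera, which compares a list with the other bins, called 0 lists, with a lowest adjusted p of 0.172 with its preset correlation and 0.808 with an estimated correlation.

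Among the 17 hypoxia-inducible genes, 14 had a higher and 3 a lower mean in Phd2 heterozygous tumours and 0 passed. Of all bins 75.2% were higher, and the count of each list is to be set against that share. It includes bins of low 5hmC, where the mean difference was 0.00186 percentage points in the lowest class. The lists lay at 0.858 (Polycomb) to 1.75 (tumour suppressor) times the genome-wide mean, all but Polycomb above it. The share among bins of like level was not computed, so a count above 75.2% does not set a list apart. The bin of Adm, which encodes the vessel-active peptide adrenomedullin, held 6.64% ± 1.27 (SD, n = 4) against 4.23% ± 0.449 (SD, n = 3). That of the glycolytic gene Pgk1 held 5.08% ± 0.347 against 3.16% ± 0.490. Of 12 endothelial genes 9 were higher and 3 lower. Values were 3.08% ± 0.522 against 1.29% ± 0.524 at Esam and 7.0% ± 0.525 against 5.45% ± 0.864 at Pecam1, both genes of endothelial cell contacts. Of 12 genes of the cytosine modification list 9 were higher. They included 6.0% ± 0.912 against 3.51% ± 0.509 at the dioxygenase gene Tet3 and 4.41% ± 0.833 against 2.80% ± 0.328 at the glycosylase gene Tdg. The Polycomb target list had 11 of 14 genes higher, with 3.51% ± 0.898 against 2.74% ± 0.211 at Lhx1. Immune genes were higher for 7 of 9. The levels were 3.59% ± 0.295 against 1.80% ± 0.393 at Cd14 and 4.95% ± 1.68 against 3.4% ± 1.63 at Itgam. Luminal genes were higher for 10 of 12, and tumour suppressors for 14 of 15. Housekeeping genes were higher for 9 of 10, led by B2m (4.99% ± 0.926 against 3.32% ± 0.488) and Psmb2 (5.39% ± 0.439 against 3.98% ± 0.446). Fibroblast genes were higher for 8 of 8, led by Pdgfra (3.52% ± 1.03 against 2.35% ± 0.377) and Col1a1 (5.02% ± 1.98 against 4.01% ± 1.31). Basal epithelial genes were higher for 5 of 7, led by Mylk (5.86% ± 1.95 against 4.22% ± 0.431) and Krt14 (4.58% ± 0.980 against 3.70% ± 0.326). Over all bins 0 of the 116 listed genes passed with limma. When adjusted over the list alone, those passing among the genes reported here were Gata3 (luminal), Esam (endothelial), Tet3 (cytosine modification) and Cd14 (immune). Adjusted over all 116 listed genes, they did not pass (limma adjusted p = 0.0933 for Gata3, Esam and Tet3 and 0.0974 for Cd14). The bin of Egln1, the gene of PHD2, held 5.53% ± 2.39 against 4.34% ± 1.24, which does not check the genotype.

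Of the 8576 bins, 0 differed between Phd2 heterozygous and wild-type tumours with limma at an adjusted p under 0.05, while 930 had an unadjusted p under 0.05, 892 of them higher and 38 lower. With 1 tumour left out, that unadjusted count ran from 463 (wild type 2) to 1210 (heterozygous 4). The 5 higher bins with the smallest p did not pass, each with an adjusted p of 0.324. The first, on chromosome 14 from 16200001 to 16500000 with Rarb and Top2b, held 5.80% ± 0.333 (SD, n = 4) against 2.88% ± 0.476 (SD, n = 3). On chromosome 6 a bin of the Klra receptor cluster, from 129900001 to 130200000, held 2.78% ± 1.71 against 0.391% ± 0.677. Also on chromosome 6, the bin of Pde1c, from 55800001 to 56100000, held 5.86% ± 1.42 against 2.10% ± 0.974. Lasp1 and Rpl19 lay in a bin of chromosome 11, from 97800001 to 98100000, with 5.82% ± 1.46 against 2.87% ± 0.589. Zfp619 and Zfp939 lay in a bin of chromosome 7, from 39300001 to 39600000, with 3.42% ± 1.08 against 0.885% ± 0.868. The 5 lower bins with the smallest p also did not pass (adjusted p from 0.324 to 0.350). They held Nrg1, Asmt, Xkr4 and Kcns3 or, on chromosome 11 from 66600001 to 66900000, no gene. At Nrg1, on chromosome 8 from 32700001 to 33000000, the values were 0.946% ± 0.591 and 2.41% ± 0.979. In simulated data of this design, limma recovered 22% of bins raised by 2 percentage points and 90% of those raised by 4. Joined to 868 windows of 3 Mb, an alternative, 206 windows were higher and 0 lower in heterozygous tumours. The count was 1 with these 7 tumours fitted alone and, with 1 tumour left out, ran from 0 (wild type 2, wild type 3 or heterozygous 1) to 480 (heterozygous 4).

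The comparison of sFlk1 with empty vector tumours asks the same of tumours made more hypoxic. Mean 5hmC was 2.46% ± 0.0670 (SD, n = 3) in sFlk1 tumours and 2.68% ± 0.158 (SD, n = 3) in empty vector tumours, a difference of -0.219 percentage points (SE 0.0992) or -8.17%. Bins of the highest class held 4.69% ± 0.271 and 5.28% ± 0.329, and those of the lowest class 0.727% ± 0.0524 and 0.657% ± 0.0539. All 3 sFlk1 tumours lay below all 3 empty vector tumours, and the exact two-sided permutation p was 0.10, the smallest that 3 against 3 can give, so this design cannot reach 0.05. The adjusted p per class was 0.167 for the 3 classes with the highest 5hmC, 0.50 for class 2 and 0.375 for class 1, and the gap between the highest and the lowest class differed by -0.659 percentage points in sFlk1 tumours (SE 0.250, exact permutation p = 0.10). Of all bins, 59.5% had a lower mean in sFlk1 tumours (exact permutation p = 0.10). Part of the difference rested on empty vector tumour 1: without it the genome-wide difference was -0.128 percentage points (exact permutation p = 0.20) and 53.9% of bins were lower (exact permutation p = 0.30).

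On the chromosomes, 19 of 20 had lower means in sFlk1 tumours and 0 passed with limma, 1 having an unadjusted p under 0.05; relative to each tumour's mean 0 passed either. Chromosome 18 had the largest difference, 2.67% ± 0.0361 (SD, n = 3) against 3.03% ± 0.129 (SD, n = 3; difference -0.359, SE 0.160, limma adjusted p = 0.217), and X the smallest, 1.38% ± 0.0846 against 1.37% ± 0.0874 (limma adjusted p = 0.968).

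In the bins of listed genes, 5hmC did not pass any test in sFlk1 tumours. Of the 116 genes, 0 passed over all bins and 0 when adjusted over the list alone. Of the 10 lists, 0 passed by camera (lowest adjusted p = 0.612, and 0.940 with an estimated correlation) or by fry (0.791). By the exact permutation test 0 passed too (lowest adjusted p = 0.833). That outcome was fixed in advance, since its smallest p with 3 against 3 is 0.10. The counts that follow are to be set against the 59.5% of all bins that were lower in sFlk1 tumours. That share too mixes bins of low and high 5hmC, and in the lowest class sFlk1 tumours had the higher mean. The share among bins of like level was not computed. Endothelial genes had a lower mean for 9 of 12, with 3.24% ± 1.14 (SD, n = 3) against 4.52% ± 0.977 (SD, n = 3) at Vwf and 4.84% ± 1.06 against 5.99% ± 0.810 at Eng. Luminal genes had a lower mean for 10 of 12, with 5.15% ± 0.160 against 6.90% ± 1.06 at Gata3 and 1.43% ± 0.555 against 2.27% ± 0.485 at the milk protein gene Wap. Tumour suppressors were lower for 11 of 15, with 6.47% ± 1.87 against 8.17% ± 1.57 at Rb1. Hypoxia-inducible genes were higher for 10 of 17, led by the oxygen sensor gene Egln3 (7.28% ± 1.33 against 4.82% ± 0.234) and Pgk1 (4.40% ± 0.862 against 2.97% ± 0.939). Fibroblast genes were higher for 5 of 8, led by Thy1 (2.69% ± 0.800 against 1.48% ± 0.327) and Dcn (3.36% ± 1.16 against 2.31% ± 0.365). Immune genes were higher for 6 of 9, led by Lyz2 (4.62% ± 1.36 against 3.39% ± 0.776), with 3.10% ± 0.922 against 3.94% ± 1.51 at Itgam. Polycomb targets were lower for 10 of 14 (Neurog1 2.38% ± 0.551 against 3.10% ± 0.438, Pax6 3.18% ± 0.256 against 3.76% ± 0.765). Cytosine modification genes were lower for 7 of 12 (Uhrf1 3.35% ± 0.257 against 3.92% ± 1.39, with Tdg at 3.33% ± 0.243 against 2.69% ± 1.07). Housekeeping genes were lower for 7 of 10 (Hprt 1.12% ± 0.832 against 2.12% ± 0.358, with Gapdh at 5.59% ± 0.0939 against 4.00% ± 1.26). Basal genes were lower for 4 of 7 (Trp63 4.20% ± 1.05 against 5.77% ± 1.21, with Acta2 at 4.29% ± 0.267 against 3.73% ± 0.525).

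In the single bins, 1 of 8576 differed between sFlk1 and empty vector tumours with limma, on chromosome X from 125100001 to 125400000, a bin without an annotated gene. It held 10.0%, 6.25% and 8.33% in the empty vector tumours and 0%, 0% and 1.64% in the sFlk1 tumours (difference -7.65, SE 0.668, limma adjusted p = 7.84e-08), and 0% in all 7 tumours of the Phd2 model. With 0 in 9 of 13 tumours it was a sparse bin, and among the 7338 bins above 0 in all 13 tumours limma called 1 other bin, higher in sFlk1 tumours. At an unadjusted p under 0.05 there were 616 bins, 434 of them lower and 182 higher. The next bins did not pass, with limma adjusted p from 0.253 to 0.356 for those lower in sFlk1 tumours. The bin of Sem1, on chromosome 6 from 6300001 to 6600000, held 2.41% ± 0.698 against 5.52% ± 0.844 (SD, n = 3 and 3). That of Aftph and Lgalsl, on chromosome 11 from 20700001 to 21000000, held 3.92% ± 0.903 against 7.87% ± 1.29. A bin without a gene on chromosome 4, from 81900001 to 82200000, held 2.95% ± 1.80 against 7.14% ± 0.917. The bin of Chd9, on chromosome 8 from 90600001 to 90900000, held 1.55% ± 0.886 against 4.37% ± 1.01. The 5 higher bins with the smallest p lay on chromosome 1 from 47700001 to 48000000 (2.44% ± 0.319 against 0.489% ± 0.374, limma adjusted p = 0.166), on chromosome 14 at 2 places, on X and on chromosome 5, the last 4 in clusters of predicted or Pramel genes. The 2 bins of chromosome 14 were sparse too, with 0 in 10 and 11 of 13 tumours. Simulated bins raised by 2 percentage points were recovered in 2% of cases in this comparison and those raised by 4 in 83%.

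Set together, the 2 models tested whether 5hmC was higher in the better oxygenated arm. The mean of the 2 within-model differences, Phd2 heterozygous minus wild type and empty vector minus sFlk1, was 0.373 percentage points (SE 0.0918), and the exact two-sided permutation test with labels permuted within each model gave p = 0.00571 over 700 arrangements. In the highest level class it was 0.935 (SE 0.218, exact permutation p = 0.00143, the smallest possible) and in the lowest -0.0342 (SE 0.0302, exact permutation p = 0.347). The combined genome-wide difference kept its direction and an exact p under 0.05 with any 1 tumour left out, between 0.322 and 0.428 percentage points. The Phd2 effect exceeded the sFlk1 effect by 0.308 percentage points (SE 0.184, exact permutation p = 0.320). Labels were permuted within each model, so this p refers to no effect in either model. It cannot decide whether the 2 effects differ in size. In single bins, the difference between models passed with limma in 1 bin, the sparse one on X, and 427 bins had an unadjusted p under 0.05.

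The control groups themselves differed by 0.340 percentage points (SE 0.121), with 2.68% in empty vector and 2.34% in Phd2 wild-type tumours (n = 3 and 3, exact permutation p = 0.10, the smallest possible). They differ in age, 12 against 16 weeks, and in plasmid injection, which cannot be separated here. With limma 2 bins were higher in empty vector tumours, the sparse bin on X and the last, incomplete bin of chromosome 14, from 124800001 to 124902244, and 469 bins had an unadjusted p under 0.05.

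X carried less 5hmC than the autosomes in every group. The ratio of X to autosomes was 0.544 ± 0.0507 (SD, n = 3) in sFlk1 and 0.494 ± 0.00238 (SD, n = 3) in empty vector tumours (exact permutation p = 0.10, the smallest possible). It was 0.451 ± 0.0207 (SD, n = 4) in Phd2 heterozygous and 0.479 ± 0.0173 (SD, n = 3) in wild-type tumours (exact permutation p = 0.143). The sFlk1 difference in this ratio, 0.0494, was 0.0209 without sFlk1 tumour 1, whose ratio was 0.601, and the Phd2 difference, -0.0277, was -0.0177 without heterozygous tumour 2. The difference between models in this ratio had an exact permutation p of 0.687, whose null is no effect in either model and not equal effects. At chromosome ends, the last 3 Mb exceeded the rest of the chromosome by 0.0345 ± 0.0984 percentage points (SD, n = 3) in sFlk1 and 0.0914 ± 0.0495 in empty vector tumours (exact permutation p = 0.40). They exceeded it by 0.0652 ± 0.0274 (SD, n = 4) in Phd2 heterozygous and 0.0508 ± 0.0140 (SD, n = 3) in wild-type tumours (exact permutation p = 0.457). The difference between models at the ends had an exact permutation p of 0.581, with the same limit.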

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

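The tests in this part were chosen after the results were seen, except the bin test of the difference between models. The bin on chromosome X from 125100001 to 125400000 stood out because the effects in the 2 models differed by -7.65 percentage points (SE 0.915, limma adjusted p = 5.62e-05). Among 79 bins at 0 in 7 or more tumours, 12.7% held a value of 10% or more in some tumour, against 1.19% of the other 8497 bins, and leaving out bins with a 0 in any tumour removes this bin by construction. A sparsely read bin is therefore a candidate explanation. The 3 high values, 10.0%, 6.25% and 8.33%, are such as single calls among few could give, but counts are unknown. They all fell in the empty vector group, and no biological explanation was tested. Other splits of the tumours gave as many calls in this test in 24 of 100 drawn (real 1, highest other 4), so chance is not excluded. In the sFlk1 comparison 4 of 10 splits gave as many bins (real 1, highest other 2), and 10 splits are too few for a share under 0.05.

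5hmC was higher in the better oxygenated arm of both models. A background added equally to every bin, such as uneven conversion of unmodified cytosine, would leave the gap between high and low bins unaltered, whereas that gap was 0.969 percentage points wider in the better oxygenated arm (SE 0.224, exact permutation p = 0.00143). A single capture or conversion factor per library with no background would leave the ratio of high to low bins unaltered, whereas its log2 was 0.34 higher (SE 0.10, exact permutation p = 0.0114). Neither test addresses a background that differs between bins as well as between libraries, so that stays open. A factor over a constant background stays open too. In either model 0 of 20 chromosomes changed relative to the tumour's mean, which decides nothing, since such a factor would also change a low chromosome such as X by a smaller share than the mean, and no spike-in value was used here. A changed mixture of cell types also cannot be told apart. Taken as a ratio to the genome mean, the cell type lists had a lowest adjusted exact permutation p of 0.857. Taken as a difference from that mean, the lowest was 0.286, for the luminal list in the Phd2 model. A list of bins that does not pass excludes nothing. A difference in oxygenation, which the design names, stays open beside these.

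Splits of the 7 tumours of the Phd2 model bear on the limma counts. As many chromosomes were called in 3 of 35 splits (real 19, highest other 20), as many 3 Mb windows in 2 (real 206, highest other 489), and as many lists by fry in 2 (real 4, highest other 7), so chance is not excluded for these. The count of bins was 0 in the real split (highest other 2), so 35 of 35 splits gave as many by construction, which tests nothing. The split with 489 windows sets heterozygous tumours 1 to 3 against the wild-type tumours together with heterozygous tumour 4, which points to a structure of the samples of unknown source. Tumour 4 had the lowest mean of its group, 2.54%, but in the highest class 5.48%, above every wild-type tumour. It also had 358 bins at 0, against 74 to 263 in the other heterozygous and 105 to 184 in the wild-type tumours. Whether this count reflects depth was not tested. In the sFlk1 model the real counts of chromosomes, 3 Mb windows and lists by fry were 0, so 10 of 10 splits gave as many by construction; the highest of the other splits were 0, 1 and 0, and 10 splits are too few to reach a share under 0.05. Among 38 measures per tumour, 0 heterozygous tumours stood far from the others of their group by Dixon's test.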

How the results depend on the processing

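Of the alternative values, 288 were counted as unaltered: differences and shares that kept direction and side of the threshold, and counts of calls within 1.5 times the main count, whichever bins were called and in whichever direction. This says nothing of stability for results that did not pass, such as the genome-wide difference within either model. The combined difference of both models ranged from 0.297 with medians (exact permutation p = 0.0157) to 0.431 with bins above 0 in all tumours (p = 0.00571). Settings that changed other results follow, and the cause was not tested unless given. Leaving out bins with a 0, chosen after seeing the data, turned the sFlk1 difference at chromosome ends to 0.0247 and the difference between models there to 0.0292, and ended the bin call between models (0). The sFlk1 count stayed 1, but that bin was higher in sFlk1 tumours, where the main call was lower. Leaving out 1 tumour, added after seeing the data for X, the ends and the gap between classes, gave 0.00777 to -0.0906 for that difference at the ends and 0.0416 to -0.00684 for the difference between models in the X ratio, both reversed without sFlk1 tumour 1. Within models it gave -0.128 to -0.275 for the sFlk1 genome-wide difference and 0.425 to 0.637 for Phd2, and at the ends -0.00669 to -0.105 for sFlk1 and 0.00377 to 0.0245 for Phd2. It gave 1.01 to 1.45 for the Phd2 difference between highest and lowest class, past the threshold in no case because fewer arrangements remain.

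Counts of bins were 1 to 4 for sFlk1 with 1 tumour left out (4 without sFlk1 tumour 1), 0 to 1 for Phd2 (1 without heterozygous tumour 3) and 1 to 2 between models (2 without sFlk1 tumour 1 or 3). With log2(percentage + 0.1) they were 0, 1 and 0, with log2(percentage + 0.5) 1 for Phd2, and joined to 3 Mb 0, 206 and 0. The 206 windows, whose own alternatives were chosen after seeing the data, became 0 scaled to the sample median, 446 with sample weights, 1 with the 2 groups fitted alone, and 0 to 480 with 1 tumour left out (16 without wild type 1, 1 without heterozygous 2); sFlk1 gave 0 in each. The 19 chromosomes became 0 relative to the tumour's mean. Scaling to the sample median moved the Phd2 split of bins with unadjusted p under 0.05 from 892 higher and 38 lower to 174 and 157, and the sFlk1 split from 182 and 434 to 329 and 255.

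Replicate numbers do not pair the tumours: same-numbered deviations correlated at -0.0934 to -0.00429 (Phd2) and -0.0526 to -0.0421 (sFlk1), below all differently numbered sFlk1 pairs. As a block, the number gave 1, 0 and 1 bins, 19 Phd2 chromosomes and 447 Phd2 windows, these 2 added after seeing the data, the block leaving heterozygous tumour 4 without a partner. Paired genome-wide differences were -0.219 and 0.637, each with exact p = 0.25, the smallest possible. Depth, unknown here, limits what single bins can show.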

Other observations

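The landscape of 5hmC was shared by all groups, and the bins named here were chosen after their values were seen. Among bins above 0 in all 13 tumours, the highest mean, 11.7% ± 2.13 (SD, n = 13), 4.51 times the genome mean, lay on chromosome 4 from 82200001 to 82500000 at Nfib, which encodes a nuclear factor I transcription factor. It was followed by bins at Auts2 (chromosome 5, 132300001 to 132600000, 10.3% ± 2.14), Trps1 (chromosome 15, 50700001 to 51000000, 9.85% ± 1.85) and Snd1 (chromosome 6, 28500001 to 28800000, 9.13% ± 1.33). The top 20 also held transcription factor genes Etv6 (8.80% ± 2.22), Nfia (8.50% ± 2.51), Tcf7l2 (8.07% ± 1.58) and the epithelial factor Grhl2 (7.93% ± 1.82). The bins of Etv6 and Grhl2 hold other genes too, and further top bins held genes of other kinds, such as Gnaq, Chrm3 and Pik3r1. Whether transcription factor genes were more frequent there than elsewhere was not tested. At Nfib the group means were 12.7% in Phd2 heterozygous, 9.90% in Phd2 wild-type, 13.2% in empty vector and 10.9% in sFlk1 tumours. At Rad51b, on chromosome 12 from 79500001 to 79800000, they were 8.03%, 7.95%, 8.25% and 8.12%. By chromosome the mean over 13 tumours ran from 1.31% ± 0.115 on X to 3.16% ± 0.301 on chromosome 19.

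The tests of gene content were chosen after the result was seen, and that of shared regions before; its further settings came after. 5hmC may follow gene content: bins of the highest level class held 3.43 protein-coding genes on average and those of the lowest 1.13, a ratio of 3.04, and 10.0% against 65.0% of bins had no gene (Spearman's rho across bins 0.440, bins not being independent). More genes in the highest class were found on 18 of 20 chromosomes, not on 2 and 13, and class 4 held more, 3.94, so the relation across chromosomes stays open.

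A second hypothesis was that regions beyond the general level move together in the 2 models, which share no tumours. Across 868 windows of 3 Mb, relative to each tumour's mean and with the trend on level removed, the Phd2 and sFlk1 effects, each taken as better minus less oxygenated, correlated with r = 0.124 (exact permutation p = 0.0429, 700 arrangements). With trends of degree 1 to 3, with or without X, r was 0.117 to 0.124 and p 0.0429 to 0.0457 in all 6 settings. Shared regional effects may thus exist, but the correlation is small and its p lies just under 0.05 and is not adjusted for the other tests made. With the trend on level left in, r was 0.200 relative to each tumour's mean (exact permutation p = 0.00286), and on percentages, neither relative to that mean nor with the trend removed, 0.527 (exact permutation p = 0.00571).

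Outside the comparisons, 85 of 306 bins of chromosome Y held a value above 0 in some tumour, with 6 to 15 such bins per tumour. The means over these bins were 2.96% ± 1.96 (SD, n = 4) in Phd2 heterozygous, 1.96% ± 0.966 (SD, n = 3) in wild-type, 1.62% ± 0.508 in empty vector and 1.52% ± 0.790 in sFlk1 tumours, with exact permutation p = 0.514 and 0.90 in the 2 models.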
